A study of Bos taurus with 16 samples.

How the data were processed

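Total RNA from endometrial biopsies of 16 heifers was sequenced by the authors on a DNBSEQ instrument as paired-end reads of 100 bp, from RNA with integrity numbers between 8 and 9.9, per the submitters' protocol. The design text gives 6 heifers per treatment, and RNA of 4 per group was sequenced. The deposited table gives expected counts per gene and sample, as estimated by the authors and not normalised between samples. The same deposited table gives TPM per gene and sample, computed by the authors, which were used here only to check the counts. Per the submitters' processing notes the tools were HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.8 and DESeq2, the last with no version, and their roles are not stated; the genome build and annotation are not given in the sources used here, so no coordinates are printed. The authors' deposited comparison tables hold a log2 fold change of 1 group over another for each gene, as computed by the authors. They also hold a p-value and a q-value of the authors for each gene, and the test behind them is not stated. The 16 per-sample FPKM columns were not used here. The labels write the group with PAG as IFNT+PAG and its sample titles as PSPB6, after pregnancy-specific protein B.

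The table names 18344 genes, of which 1 has no values, which left 18343. Every gene in it has a read in at least 1 BSA3 or IFNT3 library (0 genes lack one), while 331 genes have none in IFNT6 and IFNT+PAG, and the TPM of day-20 libraries sum to 7.3 to 24.4 short of 1e6. A gene read only on day 20 would therefore be missing from the table, and no statement here covers such genes. Between 93.8% and 94.5% of the values of a sample were whole, and expected counts were rounded to whole numbers. Gene numbers were matched to RefSeq for 17439 genes (95.1%). Libraries were checked for duplicates: the lowest chi-square per degree of freedom between libraries of 1 group was 47.0, where repeated sequencing of 1 library would give about 1. Replicate numbers follow the order of the records and pair no animals.

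Genes were kept by edgeR's filterByExpr, which left 15745, and libraries were scaled by TMM. All 16 libraries went into a single quasi-likelihood model with a mean per group (edgeR 4.0.16 with robust dispersions, limma 3.58.1, R 4.3.3); the common biological coefficient of variation was 0.45. Contrasts of IFNT3 minus BSA3, IFNT6 minus IFNT3, IFNT+PAG minus IFNT6 and IFNT6 minus BSA3 were tested by edgeR's two-sided quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are given with a standard error worked back from the test, as the absolute log2 fold change over the square root of F. CPM is given as mean ± SD over 4 libraries. Expression at the level of libraries was summarised as log2 CPM with a prior count of 2, and principal components over the 1000 most variable genes put 39.5% of the variance on the first and 16.6% on the second.

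Before the data were examined, 41 gene lists, the comparisons, the rule for named genes and most alternatives were fixed. At least 3 genes were in the table for 40 lists, which were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists. They were tested again with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. Counts of members were made over all genes and again adjusted over the list alone. A list score is the mean over its genes of log2 CPM centred on each gene's mean over the 16 libraries. The leukocyte score pools 119 marker genes of leukocytes outside the classical interferon-stimulated, receptor and JAK-STAT, and interferon gamma response lists. It still holds leukocyte markers that interferon can induce, such as SIGLEC1, so it may carry part of the treatment response. The text names, per comparison, up to 10 genes higher and 10 lower with the largest change among called genes with a mean of at least 5 CPM, a symbol not starting with LOC and no overlap between the groups. It also names the 2 to 4 members of smallest p of each list described, a fixed set of 18 interferon, receptor, prostaglandin and secretion genes, and, where fewer than 10 genes passed, the 5 of smallest p that failed.

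Each total of at least 18.62 M counts sets the counting error, and in the 4 libraries of a group the spread between animals was the larger limit. Standard errors and floors do not cover error of mapping or of gene assignment. The fold of a gene without reads in a group is given as a lower bound against 3 counts over that group. That bound covers counting error in the group without reads and not the spread between animals. The procedure was tested on simulated data with the same group sizes and with 50 genes changed per step. The changed genes were drawn from those with a mean of at least 1 CPM, so the shares called do not cover weaker genes. Between 66% and 84% of genes changed by a log2 of 2 in either direction were called in the 4 comparisons, and between 10% and 28% of those changed by a log2 of 1. Between 3 and 9 unchanged genes were called per comparison, a changed list of 25 genes was found in each and 0 of 20 unchanged lists. The simulated genes varied independently of each other, so the list result does not cover lists whose genes move together.

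Alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 4 libraries, 1 surrogate variable (sva 3.50.0), only the 8 libraries compared, a minimum of 2-fold, DESeq2 1.42.0, limma-voom with sample weights, and leaving out each library in turn. After the data were seen, the leukocyte score as a covariate, a fit without the 5 libraries of highest leukocyte score and the removal of single libraries in the list tests were added. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.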

Results

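Gene expression was measured by RNA sequencing in endometrial biopsies from 16 Holstein heifers, 4 in each of 4 groups, whose uteri had been infused with proteins that a conceptus releases in early pregnancy. Interferon tau (IFNT) is the trophoblast interferon by which a ruminant conceptus prevents luteolysis, and the pregnancy-associated glycoproteins (PAG) are secreted by trophoblast cells of the placenta. BSA3 heifers received vehicle (bovine serum albumin, 200 µg/mL) on days 14 to 16 of the oestrous cycle and were biopsied on day 17. IFNT3 heifers received recombinant ovine IFNT at 10 µg/mL, or 200 µg in each 20 mL infusion, on the same days and were also biopsied on day 17. IFNT6 heifers received IFNT on days 14 to 19 and were biopsied on day 20. IFNT+PAG heifers received the same 6 days of IFNT, with PAG purified from bovine placenta at 5 µg/mL (100 µg per infusion) added on days 17 to 19, and were biopsied on day 20. Each biopsy was taken 12 h after the last infusion with forceps passed through the cervix.

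The total count per library ran from 18.62 M to 23.99 M expected counts (M, 1e6), with a median of 22.2 M, and between 16549 and 17044 genes had at least 1 read. Of 18343 genes with values, 15745 were expressed well enough to be tested. Libraries differed as much within groups as between them: the correlation of log2 expression across genes, which are not independent replicates, had a median of 0.927 for pairs of libraries of 1 group and 0.927 for pairs of different groups. A leukocyte score, the mean centred log2 expression of 119 marker genes, varied widely inside groups. It averaged -0.68 ± 0.76 (SD, n = 4) in BSA3, 0.15 ± 1.46 in IFNT3, 0.01 ± 1.06 in IFNT6 and 0.53 ± 0.87 in IFNT+PAG. It was highest in IFNT3 replicate 1 (1.95), IFNT+PAG replicate 2 (1.59), IFNT6 replicate 4 (1.57), IFNT+PAG replicate 4 (0.87) and IFNT3 replicate 4 (0.68).

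The comparison of IFNT3 with BSA3 addressed what 3 days of IFNT did to the endometrium at 1 stage of the cycle. The classical interferon-stimulated genes, most of which encode antiviral proteins, rose together: 50 of the 55 measured members were higher in IFNT3, 52 when adjusted over the list alone, and 0 were lower. RSAD2 (viperin, an inhibitor of virus replication) rose 63.1-fold, from 24.6 ± 6.58 CPM (counts per 1e6 counts of a library; mean ± SD, n = 4) in BSA3 to 1554 ± 189 in IFNT3. ISG15, a ubiquitin-like protein that is attached to other proteins after interferon exposure, rose 61.8-fold, from 11.1 ± 4.33 to 689 ± 217 CPM. The dynamin-like GTPases MX2 and MX1 rose, MX2 78.0-fold and MX1 from 149 ± 47.2 to 3430 ± 531 CPM. Among 2'-5' oligoadenylate synthetases, sensors of double-stranded RNA, OAS2 rose from 5.01 ± 1.81 to 317 ± 132 CPM and OAS1Y rose 17.3-fold. IFI6 rose 20.3-fold, DDX58 (RIG-I, a cytosolic RNA sensor) rose by a log2 fold change of 4.03 ± 0.36 (SE, adjusted p = 7.3e-05), and IFIT3 rose by 5.79 ± 0.78. The adjusted p was 7.14e-05 for RSAD2, OAS2 and IFI6, 0.00017 for ISG15, MX1 and OAS1Y, and 0.000212 for MX2, and each of these genes was higher in 4 of 4 IFNT3 libraries than in every BSA3 library. The list's median log2 fold change was 3.44 (adjusted p = 6.95e-143 by camera with a preset correlation). This was the only 1 of the 20 lists called in this comparison that also passed with an estimated correlation (adjusted p = 0.0108 with an estimated correlation). Reads of the MX, OAS1, MHC and ULBP families can be shared between close paralogs, so values for single members of these families are less certain than those of their families.

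**Figure D1:**
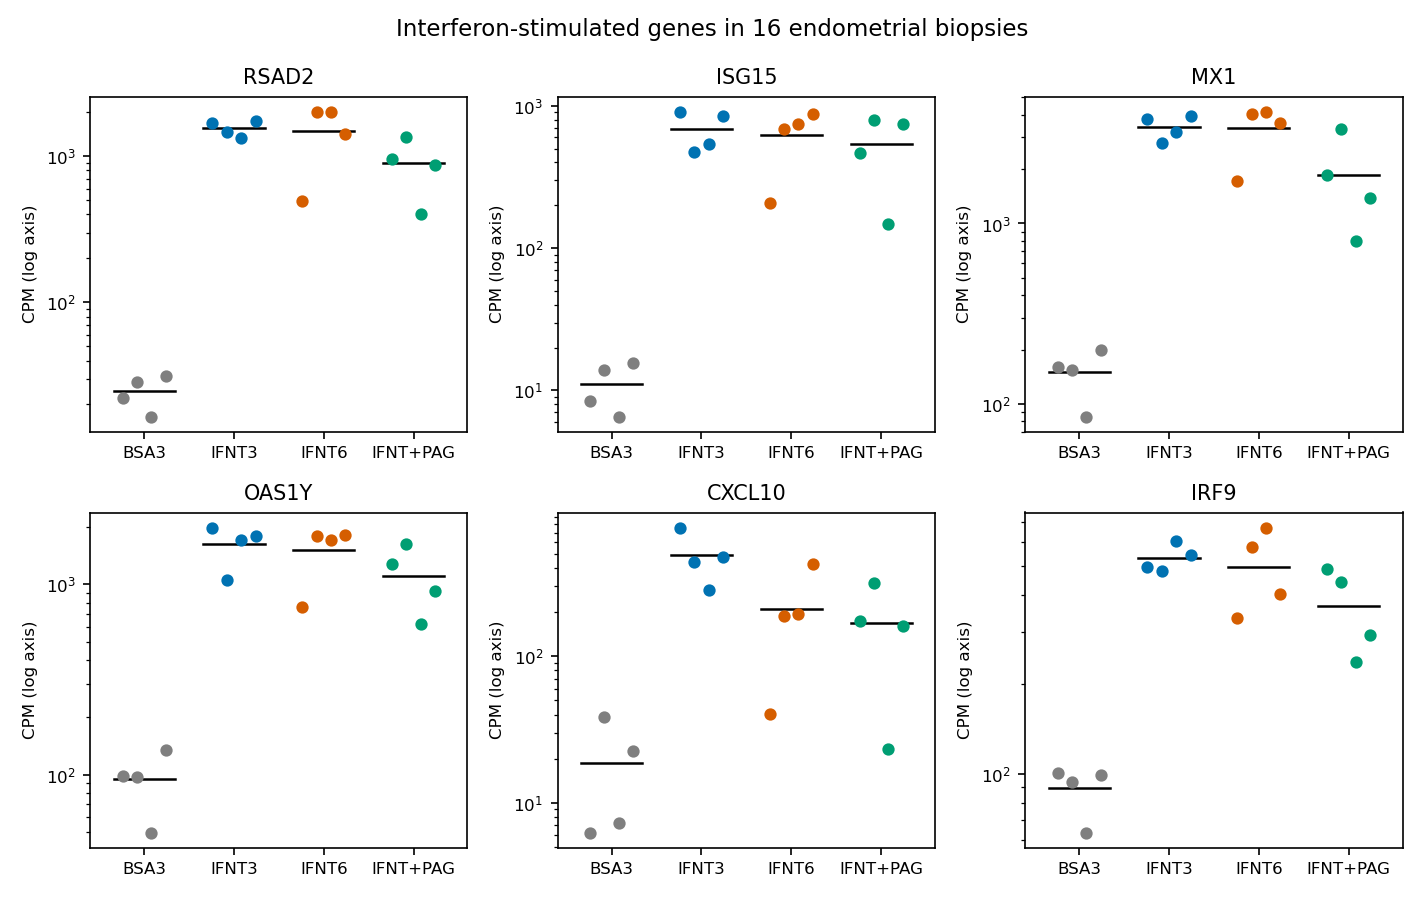
Expression of RSAD2, ISG15, MX1, OAS1Y, CXCL10 and IRF9 in the 4 groups, as CPM on a log axis, with 1 point per library and a bar at the group mean (n = 4). For RSAD2 the group means were 24.6 CPM in BSA3, 1554 in IFNT3, 1482 in IFNT6 and 900 in IFNT+PAG.

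The transcription factors that carry the interferon signal rose as well. Of 30 genes of the interferon receptor and JAK-STAT pathway 9 were higher, 14 when adjusted over the list alone, with a median log2 fold change of 0.66 (adjusted p = 3.82e-11, and adjusted p = 0.424 with an estimated correlation). IRF9, the DNA-binding part of the interferon-stimulated gene factor, rose 5.95-fold, from 89.2 ± 17.5 to 531 ± 55.7 CPM (adjusted p = 0.000186). STAT1, its partner, rose 5.12-fold (adjusted p = 0.0032), and IRF7, which amplifies interferon production, rose from 46.5 ± 4.44 to 677 ± 163 CPM (adjusted p = 0.000186). IRF3 rose by a log2 fold change of 1.54 ± 0.27 (adjusted p = 0.00542). The receptor subunits themselves did not pass the test: IFNAR1 differed by -0.30 ± 0.21 (adjusted p = 0.454) and IFNAR2 by 0.16 ± 0.38 (adjusted p = 0.865). Of 16 guanylate binding proteins and genes of the interferon gamma response 8 were higher, 12 when adjusted over the list alone, with a median of 2.55 (adjusted p = 1.7e-16, and adjusted p = 0.346 with an estimated correlation). GBP4, a GTPase of cell-autonomous immunity, rose from 25.6 ± 6.01 to 255 ± 39.2 CPM (adjusted p = 0.000376), and GBP2 rose by 3.95 ± 0.60 (adjusted p = 0.00239). CXCL10, a chemokine that draws T and NK cells, rose from 18.6 ± 15.1 to 489 ± 197 CPM (adjusted p = 0.00858). LGALS3BP, a secreted galectin-binding glycoprotein, rose by 1.77 ± 0.29 (adjusted p = 0.0041). Without the 5 libraries of highest leukocyte score CXCL10 stood at 4.22 ± 0.92 and IRF3 at 1.22 ± 0.26, and both lost their call (adjusted p = 0.0606 and 0.0559). That fit holds only 2 IFNT3 libraries, so a call can end there for lack of libraries alone. It leaves out IFNT3 libraries but no BSA3 library, so a smaller rise there of genes that follow leukocytes comes in part from that choice. Medians as far from 0 came up in 3 of the 35 splits of the 8 libraries compared for the receptor and JAK-STAT list. For the interferon gamma response list this held for the real split alone (highest other 1.87).

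Part of the genes of antigen presentation, pattern recognition and apoptosis were higher in IFNT3. These lists share members with those above and are not separate counts. IFI16 and TNFSF10 are also in the classical interferon-stimulated list, and TAP1 is also in the interferon gamma response list. Of 25 genes of MHC class I antigen processing 11 were higher, 18 when adjusted over the list alone, with a median log2 fold change of 1.01 (adjusted p = 5.46e-13, and adjusted p = 0.346 with an estimated correlation). TAP1, a subunit of the transporter that loads peptides into the endoplasmic reticulum, rose from 51.7 ± 14.3 to 293 ± 107 CPM (adjusted p = 0.00847). Its partner TAP2 rose by 1.19 ± 0.21 (adjusted p = 0.00663), and NLRC5, the transactivator of MHC class I genes, rose by 2.06 ± 0.39 (adjusted p = 0.00913). Of 14 MHC class II genes 1 was higher, 7 when adjusted over the list alone, with a median of 1.09 (adjusted p = 8.9e-05, and adjusted p = 0.613 with an estimated correlation). The called gene, BOLA-DMB, which helps to load peptides, rose by 2.02 ± 0.47 (adjusted p = 0.027). Of 29 genes of pattern recognition and the inflammasome 3 were higher, 8 when adjusted over the list alone, with a median of 1.34 (adjusted p = 2.41e-08, and adjusted p = 0.613 with an estimated correlation). IFI16, a nuclear DNA sensor, rose by 3.39 ± 0.50 (adjusted p = 0.00194), CGAS, a cytosolic DNA sensor, by 3.37 ± 0.57 (adjusted p = 0.0048), and the inflammatory caspase CASP4 by 2.73 ± 0.67 (adjusted p = 0.0386). Of 31 apoptosis genes 3 were higher, 13 when adjusted over the list alone, with a median of 0.67 (adjusted p = 1.52e-07, and adjusted p = 0.346 with an estimated correlation). These 3 were the death ligand TNFSF10 (TRAIL; 1.46 ± 0.24), the death receptor FAS (1.18 ± 0.26) and the executioner caspase CASP7 (1.33 ± 0.33). The calls of BOLA-DMB, CASP4 and CASP7 were each lost without any 1 of BSA3 replicates 1 to 4 or IFNT3 replicates 1 and 4 (highest adjusted p 0.0935, 0.121 and 0.121), and that of FAS without BSA3 replicates 1, 3 or 4 or IFNT3 replicates 3 or 4 (highest 0.0762). In the fit without the 5 libraries of highest leukocyte score, with 2 IFNT3 libraries, these 4 genes lost it too, as did TAP1, NLRC5 and TNFSF10 (adjusted p = 0.0511, 0.0511 and 0.0687). The log2 fold changes there were within 1 SE of those with all libraries for FAS (1.27 ± 0.28), CASP7 (1.11 ± 0.25), NLRC5 (1.78 ± 0.37) and TNFSF10 (1.28 ± 0.30), and smaller by more for TAP1 (1.98 ± 0.41), BOLA-DMB (1.02 ± 0.39) and CASP4 (1.67 ± 0.50). CASP7 also lost its call with upper-quartile factors and BOLA-DMB in a fit of the 8 libraries alone. The medians of MHC class II and of pattern recognition were 0.65 and 0.78 without IFNT3 replicate 1, the library of highest leukocyte score, and 0.18 and 0.19 without the 5 libraries of highest score, where neither list passed (adjusted p = 0.196 and 0.071). Medians as far from 0 came up in 7 and 3 of the 35 splits of the 8 libraries. For MHC class I and apoptosis the real split alone reached its median (highest other 0.90 and 0.62).

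Further lists of immune function, leukocyte markers and immediate early genes were higher as groups, with few genes called. Of 25 complement genes 1 was higher, 6 when adjusted over the list alone, with a median log2 fold change of 0.83 (adjusted p = 0.00522, and adjusted p = 0.613 with an estimated correlation). It was C5, the precursor of an anaphylatoxin (3.02 ± 0.72, adjusted p = 0.0321). Of 26 genes of immune checkpoints and tolerance 2 were higher, 5 when adjusted over the list alone, with a median of 0.90 (adjusted p = 0.0146, and adjusted p = 0.613 with an estimated correlation). IDO1, which degrades tryptophan and restrains T cells, rose from 3.69 ± 3.93 to 199 ± 100.1 CPM (adjusted p = 0.0169), and LGALS9, a galectin that binds the inhibitory receptor TIM-3, rose by 2.52 ± 0.47 (adjusted p = 0.00858). Of 30 immediate early genes 2 were higher, 4 when adjusted over the list alone, with a median of 0.59 (adjusted p = 0.00308, and adjusted p = 0.613 with an estimated correlation): IER2 (0.98 ± 0.23) and ZFP36, which destabilises cytokine mRNAs (1.66 ± 0.43). Markers of T and NK cells had a median of 1.57 over 41 genes (adjusted p = 2.87e-05, and adjusted p = 0.613 with an estimated correlation). By edgeR's quasi-likelihood test 0 of the 41 passed, with 15 higher at an unadjusted p under 0.05, limma-voom called 0 and DESeq2's Wald test called 7. Among these were GZMA and PRF1, granule proteins of cytotoxic lymphocytes (2.08 ± 0.65 and 2.89 ± 0.98 by edgeR, adjusted p = 0.0928 and 0.117). Markers of macrophages and dendritic cells had a median of 1.72 over 33 genes (adjusted p = 0.000112, and adjusted p = 0.613 with an estimated correlation), with 1 called, the sialic acid receptor SIGLEC1, which interferon induces (5.89 ± 1.17, adjusted p = 0.0127); MS4A7 stood at 2.54 ± 0.76 (adjusted p = 0.0786) and was called with DESeq2, 1 surrogate variable, the leukocyte covariate and without IFNT3 replicate 2. SIGLEC1 and MS4A7 are themselves part of the leukocyte score, so fits based on that score are no separate test of them. The lists of this paragraph leaned on single libraries. Without IFNT3 replicate 1, the library of highest leukocyte score, the median was 0.65 for T and NK cell markers, 0.62 for macrophage and dendritic cell markers and 0.68 for complement. All 3 lost their call (adjusted p = 0.0673, 0.121 and 0.102, the highest over the 8 removals of 1 library). The leukocyte score pools markers of T and NK cells and of macrophages and dendritic cells. The drop of those 2 lists without the library of highest score thus comes at least in part from its choice. The complement median was 0.55 without BSA3 replicate 3. The checkpoint list lost its call without BSA3 replicate 3, IFNT3 replicate 1 or IFNT3 replicate 4 (adjusted p = 0.0525, 0.146 and 0.101), and the immediate early list without IFNT3 replicate 4 (adjusted p = 0.0534). SIGLEC1 lost its call without BSA3 replicate 2, and IDO1 without BSA3 replicates 1, 3 or 4. It was lost for C5 and IER2 without any 1 of BSA3 replicates 1 to 4 or IFNT3 replicates 1 and 4, and ZFP36 without any 1 library except IFNT3 replicate 2 (highest adjusted p 0.0533, 0.0654, 0.106, 0.0924 and 0.135). In the fit without the 5 libraries of highest leukocyte score, IDO1 (4.97 ± 1.09), C5 (1.83 ± 0.72) and IER2 (0.75 ± 0.18) lost theirs. SIGLEC1 and LGALS9 kept their call in that fit, but with much smaller log2 fold changes (2.99 ± 0.57 and 1.52 ± 0.30). C5 also lost its call with the leukocyte covariate and with limma-voom, and ZFP36 with RLE or upper-quartile factors and with the filter of at least 1 CPM. The 35 splits of the 8 libraries gave medians as far from 0 in 10 for complement, 8 for checkpoints, 3 for immediate early genes, 8 for T and NK cells and 7 for macrophages, the real split included.

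Ribosomal protein genes lay lower in IFNT3 as a group, with few called. Of 76 members 10 were lower, 47 when adjusted over the list alone, and 0 were higher, with a median log2 fold change of -0.49 (adjusted p = 2.44e-19, and adjusted p = 0.573 with an estimated correlation). RPS6, the small-subunit protein phosphorylated by S6 kinase, went from 906 ± 139 to 456 ± 102 CPM (-0.99 ± 0.21, adjusted p = 0.0191), and RPL7 from 545 ± 50.1 to 257 ± 63.5 CPM (-1.08 ± 0.24, adjusted p = 0.0201). RPS8 and RPL13 fell by 1.04 ± 0.24 and 0.84 ± 0.19 (adjusted p = 0.025 and 0.0262). The median stayed between -0.55 and -0.39 with any 1 library left out, and was -0.62 with upper-quartile scaling. Only the real 1 of the 35 splits of the 8 libraries gave a median as far from 0 (highest other 0.40 in size). Each of these 4 genes lost its call without BSA3 replicate 2 or 4 or IFNT3 replicate 1, 3 or 4, and RPL13 also without BSA3 replicate 3 (highest adjusted p 0.0692 for RPS6, 0.0716 for RPL7, 0.0888 for RPS8 and 0.0881 for RPL13). All 4 also lost it in the fit without the 5 libraries of highest leukocyte score, where the folds stayed about as large (RPS6 -1.02 ± 0.26, RPL7 -0.95 ± 0.24, RPS8 -1.02 ± 0.28, RPL13 -0.92 ± 0.22) with fewer libraries.

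Markers of contractile and connective tissue and cell cycle genes were lower in IFNT3 as groups. All 23 smooth muscle markers lay below 0, with a median log2 fold change of -1.46 (adjusted p = 9.61e-06, and adjusted p = 0.613 with an estimated correlation). MYH11, the smooth muscle myosin heavy chain, stood at -2.51 ± 0.92 (adjusted p = 0.144) and SMTN at -1.72 ± 0.62 (adjusted p = 0.137). Extracellular matrix remodelling genes had a median of -0.55 over 57 genes (adjusted p = 0.000126, and adjusted p = 0.613 with an estimated correlation), and stromal fibroblast markers -0.43 over 28 genes (adjusted p = 0.000689, and adjusted p = 0.613 with an estimated correlation). The fibrillar collagen COL3A1 stood at -2.19 ± 0.65 (adjusted p = 0.0777) and the keratan sulphate proteoglycan LUM at -1.54 ± 0.47 (adjusted p = 0.0851). Cell cycle genes had a median of -0.76 over 48 genes, of which 8 lay above 0 (adjusted p = 3.98e-05, and adjusted p = 0.613 with an estimated correlation). CCNE2, which drives entry into S phase, stood at -1.01 ± 0.43 (adjusted p = 0.201) and the replication helicase subunit MCM2 at -0.33 ± 0.15 (adjusted p = 0.235). Of these 4 lists, 0 members passed by edgeR's quasi-likelihood test passed. At an unadjusted p under 0.05, 6 smooth muscle, 7 matrix, 6 stromal and 2 cell cycle genes were lower. DESeq2's Wald test called 3, 5, 3 and 0, and limma-voom 1, 2, 1 and 0. MYH11, SMTN, COL3A1 and LUM were called by DESeq2, and COL3A1 also by limma-voom and in a fit of the 8 libraries alone. Medians as far from 0 were reached in 5 of the 35 splits of the 8 libraries for smooth muscle, 9 for matrix, 8 for stromal and 9 for cell cycle genes, the real split included. The matrix median was -0.30 without BSA3 replicate 4, -0.36 without IFNT3 replicate 2 and -0.34 without IFNT3 replicate 3, and the cell cycle median -0.48 without BSA3 replicate 4. Without the 5 libraries of highest leukocyte score the cell cycle median was -1.98 and the matrix median -1.34.

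Hormone receptors and prostaglandin synthesis, the pathways through which IFNT is known to prevent luteolysis, were not called as groups. The 2 genes called in them were both higher. Of 26 genes of oxytocin and steroid signalling 2 were higher and the median was -0.05 (adjusted p = 0.794). They were STS, which releases active steroids from their sulphates (3.10 ± 0.68, adjusted p = 0.0216), and the glucocorticoid receptor NR3C1 (0.82 ± 0.20, adjusted p = 0.0401). The oxytocin receptor OXTR, which triggers luteolytic prostaglandin release, averaged 7.62 ± 5.99 CPM in IFNT3 and 26.9 ± 5.17 in BSA3, lower in 4 of 4 IFNT3 libraries than in every BSA3 library, but did not pass (-1.82 ± 0.70, adjusted p = 0.161). The oestrogen receptor ESR1 averaged 81.0 ± 34.6 against 129 ± 18.0 CPM (-0.67 ± 0.40, adjusted p = 0.361), and the progesterone receptor PGR 12.3 ± 3.16 against 8.07 ± 0.83 CPM (0.61 ± 0.21, adjusted p = 0.127). Over 31 prostaglandin genes the median was -0.03 (adjusted p = 0.372), with 0 called by edgeR's quasi-likelihood test, 4 at an unadjusted p under 0.05, 2 called by DESeq2 and 1 by limma-voom. The cyclooxygenase PTGS2 stood at -0.03 ± 0.65 (adjusted p = 0.988) and the prostaglandin E synthase PTGES at -0.80 ± 0.70 (adjusted p = 0.558). Among 50 genes of uterine secretions 1 was higher, LGALS9, and the list, with a median of 0.09, was not called. The uterine serpin SERPINA14 ranged so widely, 3086 ± 3923 against 2505 ± 2793 CPM, that no difference was detectable (0.30 ± 1.52, adjusted p = 0.94). STS lost its call without BSA3 replicates 2, 3 or 4 or IFNT3 replicate 1, and NR3C1 without any 1 of BSA3 replicates 1 to 4 or IFNT3 replicates 1 and 4 (highest adjusted p 0.0797 and 0.126). Both lost it in the fit without the 5 libraries of highest leukocyte score, with smaller folds (STS 1.46 ± 0.57, NR3C1 0.53 ± 0.20), and in a fit of the 8 libraries alone. STS also lost it with the leukocyte covariate, and NR3C1 with upper-quartile factors.

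**Figure D2:**
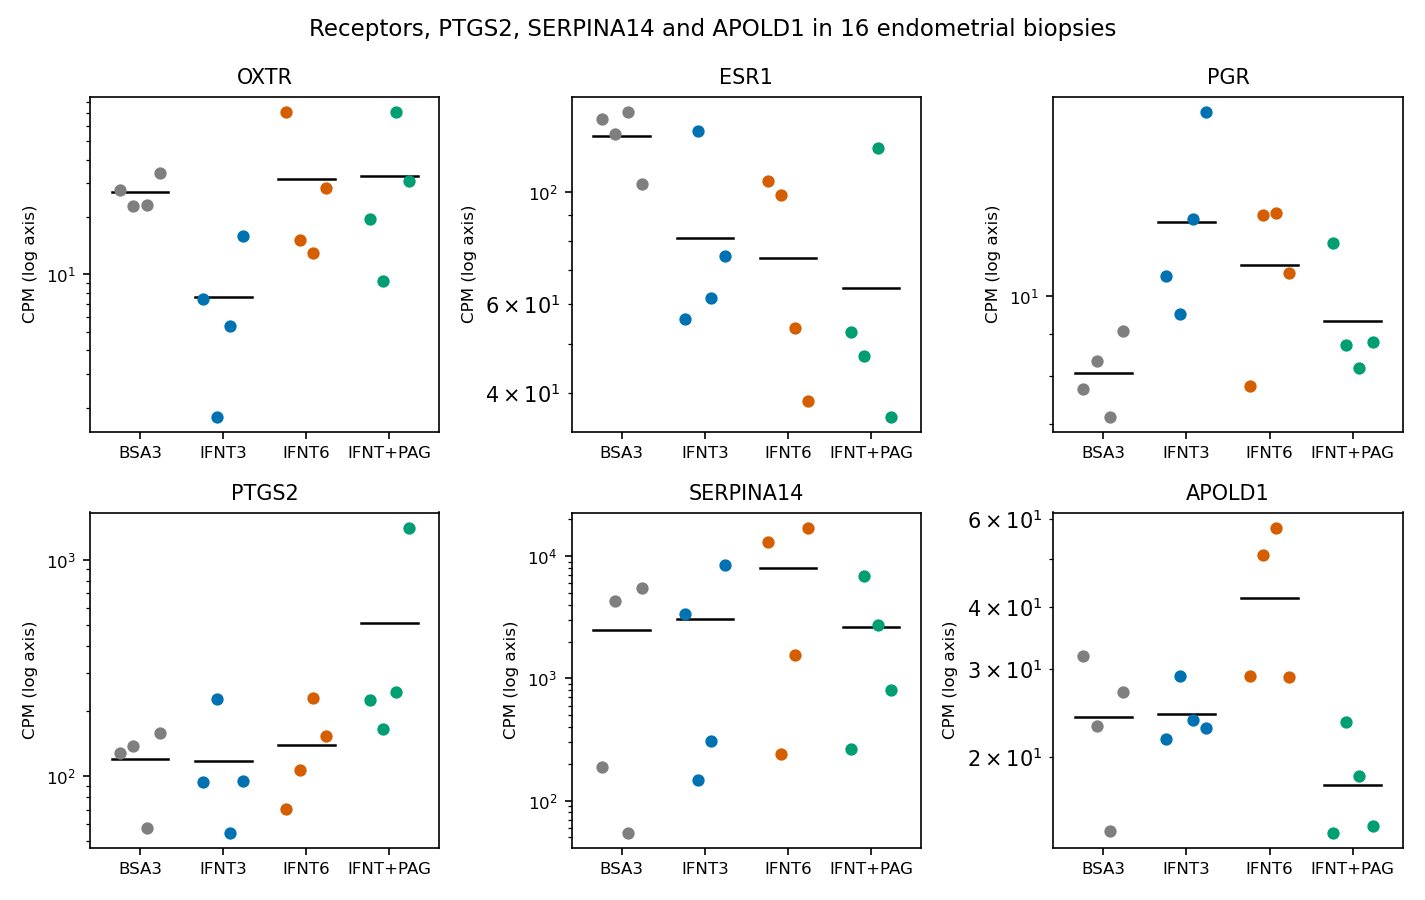
Expression of OXTR, ESR1, PGR, PTGS2, SERPINA14 and APOLD1 in the 4 groups, as CPM on a log axis, with 1 point per library and a bar at the group mean (n = 4). OXTR averaged 26.9 CPM in BSA3, 7.62 in IFNT3, 31.8 in IFNT6 and 32.7 in IFNT+PAG.

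Over all genes, edgeR's quasi-likelihood test called 572 genes between IFNT3 and BSA3 after Benjamini-Hochberg adjustment, 458 higher and 114 lower, of which 383 changed at least 2-fold (305 higher, 78 lower). Besides the genes above, the named genes with the largest rises were the C-type lectin CLEC4F, from 1.68 ± 1.53 to 298 ± 364 CPM (adjusted p = 0.0111), IFIT2 (5.90 ± 1.08, adjusted p = 0.00792) and the transglutaminase TGM7 (5.44 ± 1.19, adjusted p = 0.021). Without the 5 libraries of highest leukocyte score CLEC4F and IFIT2 kept their call. There the rise of CLEC4F was smaller, at a log2 fold change of 4.98 ± 0.85, and IFIT2 stood at 5.24 ± 0.91. The 10 named genes that fell most had log2 fold changes from -3.03 to -1.85. They were the copine CPNE5 (-3.03 ± 0.69), the mitochondrial folate enzyme ALDH1L2 (-2.39 ± 0.52), the imprinted gene MEST (-2.30 ± 0.53), STAC2 (-2.16 ± 0.52), and the adhesion molecule CNTN4 (-2.07 ± 0.51), followed by the apelin receptor APLNR (20.8 ± 6.82 to 4.97 ± 3.58 CPM), the palmitoyltransferase ZDHHC2 (-2.05 ± 0.44), C1QTNF2 (8.89 ± 2.71 to 2.25 ± 0.66 CPM), the coatomer subunit COPZ2 (51.1 ± 14.3 to 13.8 ± 5.57 CPM) and SLC26A10 (-1.85 ± 0.37). C1QTNF2, COPZ2 and SLC26A10 kept their call with any 1 library left out (highest adjusted p 0.0335, 0.0357 and 0.0488) but lost it without the 5 libraries of highest leukocyte score (adjusted p = 0.0647, 0.0554 and 0.0819). There, with 2 IFNT3 libraries, they stood at -2.02 ± 0.46, -1.95 ± 0.41 and -1.59 ± 0.41, about as far from 0 as with all libraries (-1.98 ± 0.36, -1.89 ± 0.35 and -1.85 ± 0.37). The other 7, and TGM7, each lost it in 3 or more of the 8 removals, with a highest adjusted p from 0.0725 (ZDHHC2, without IFNT3 replicate 4) to 0.123 (APLNR, without BSA3 replicate 2), and each of the 8 libraries ended at least 1 of these calls. All of these 8 except CNTN4 also lost it without the 5 libraries of highest leukocyte score, with log2 fold changes that, apart from APLNR, stayed within 1 SE of those with all libraries (ALDH1L2 -2.51 ± 0.66, CPNE5 -2.46 ± 0.66, STAC2 -2.04 ± 0.54, MEST -1.98 ± 0.60, ZDHHC2 -1.75 ± 0.42, APLNR -1.59 ± 0.46, TGM7 4.73 ± 1.25). CNTN4 lost it with the leukocyte covariate, APLNR in a fit of the 8 libraries alone, and TGM7 and CPNE5 with limma-voom. The 2 groups did not overlap in 2300 genes, 14.61% of those tested, where chance gives 2.86%, and 563 of the called genes were among them. Leaving out 1 library moved the count over 1.5-fold for 7 of 8 libraries: 245, 256 and 231 genes without BSA3 replicates 2, 3 and 4, and 272, 917, 368 and 276 without IFNT3 replicates 1, 2, 3 and 4. With upper-quartile scaling the median of all genes moved from 0.04 to -0.08 and the calls were 338 higher and 213 lower, so the share of higher genes rests on the scaling. The authors' deposited table lists 2024 genes at q under 0.05 for this comparison, 1100 higher and 924 lower, and holds all 572 genes called here.

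The comparison of IFNT6 with IFNT3 addressed whether 6 days of IFNT left the endometrium in a different state from 3 days. The interferon response stood at about the same height after both courses: MX1 averaged 3378 ± 1137 CPM in IFNT6 and 3430 ± 531 in IFNT3 (log2 fold change -0.02 ± 0.39), RSAD2 1482 ± 718 and 1554 ± 189 (-0.07 ± 0.40), and ISG15 625 ± 289 and 689 ± 217 (-0.14 ± 0.49). MX2, OAS1Y, IFI6, STAT1 and IRF9 differed by -0.17 ± 0.55, -0.10 ± 0.36, -0.01 ± 0.33, -0.07 ± 0.36 and -0.10 ± 0.26. CXCL10 averaged 212 ± 158 CPM in IFNT6 against 489 ± 197 (-1.21 ± 0.76), and OXTR 31.8 ± 26.9 against 7.62 ± 5.99 CPM (2.06 ± 0.71), each with an adjusted p of 0.981. By edgeR's quasi-likelihood test 0 genes passed, with 732 at an unadjusted p under 0.05 and a smallest adjusted p of 0.981. Limma-voom also called 0 and DESeq2's Wald test 11 (6 higher, 5 lower).

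Markers of ciliated epithelial cells, which move fluid over the endometrial surface, were lower in IFNT6 as a group: all 24 lay below 0, with a median log2 fold change of -0.71 (adjusted p = 5.65e-08, and adjusted p = 0.969 with an estimated correlation). CCDC39, which sets the length of the axonemal repeat, stood at -0.75 ± 0.34 and CAPSL at -1.04 ± 0.57. Ribosomal protein genes had a median of 0.16, with 69 of 76 above 0 (adjusted p = 5.41e-07, and adjusted p = 0.969 with an estimated correlation), RPL23A at 0.53 ± 0.20 and RPL21 at 0.46 ± 0.19. By edgeR's quasi-likelihood test, DESeq2 and limma-voom 0 members of either list passed. At an unadjusted p under 0.05, 1 ciliated marker was lower and 3 ribosomal genes were higher. With 1 library left out, the ciliated median ran from -0.95 to -0.48 and the ribosomal median from 0.11 (without IFNT3 replicate 3) to 0.24, and both lists kept their call. The kept calls are weak support, since camera at the preset correlation also called 6 to 24 lists in each of the other 34 splits. With fry 0 of the 40 lists were called in this comparison. Among the 35 splits, medians as far from 0 were reached in 6 for ciliated and 10 for ribosomal genes, and for the 4 lists below in 22 (interferon-stimulated), 3 (fatty acid), 15 (smooth muscle) and 8 (stromal). Of the other 4 lists called, the 55 interferon-stimulated genes had a median of -0.17 (adjusted p = 0.00846), with TRIM25, the ligase that activates RIG-I, at -0.50 ± 0.27. The 44 genes of fatty acid and cholesterol metabolism had a median of -0.25 (adjusted p = 0.00846), with the triglyceride enzyme DGAT2 at -1.54 ± 0.72 and the sterol regulator SREBF2 at -0.38 ± 0.20. Smooth muscle markers had a median of 0.62 (adjusted p = 0.00846; MYH11 1.04 ± 0.88, PGM5 0.94 ± 0.53) and stromal fibroblast markers 0.30 (adjusted p = 0.0205; MFAP4 0.75 ± 0.47, LUM 0.66 ± 0.46). For each of these 4 lists the adjusted p was 0.969 with an estimated correlation. Each also lost its call without single libraries. The classical interferon-stimulated genes lost it without IFNT3 replicate 1 (adjusted p = 0.551), IFNT3 replicate 4 (0.162) or IFNT6 replicate 1 (0.745, where the median was 0.07). Its median was -0.28 without IFNT3 replicate 2 and -0.36 without IFNT6 replicate 4. Fatty acid and cholesterol metabolism lost it without IFNT3 replicate 2 (0.124, median -0.10). The call of the smooth muscle markers was lost without IFNT3 replicate 2 (0.0995), IFNT3 replicate 4 (0.223) or IFNT6 replicate 4 (0.634, median 0.02). Stromal fibroblast markers lost it without IFNT3 replicate 2 (0.154), IFNT3 replicate 3 (0.173, median 0.12), IFNT6 replicate 1 (0.33) or IFNT6 replicate 3 (0.0943), and had a median of 0.47 without IFNT3 replicate 4.

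The 5 named genes of smallest p failed edgeR's test, each with an adjusted p of 0.981, and all 5 were among the 11 genes that DESeq2's Wald test called. FAM84A averaged 55.1 ± 11.4 CPM in IFNT6 and 196 ± 104 in IFNT3 (-1.83 ± 0.36), and TDRD9, a helicase of the piRNA pathway, 0.25 ± 0.12 and 6.95 ± 8.63 CPM. ULBP27, of a family of ligands for the NK cell receptor NKG2D, had 84 reads over the 4 IFNT6 libraries and 0 over the 4 IFNT3 libraries. In pooled reads it was at least 27.7-fold higher in IFNT6, against a floor of 3 counts over the group. That bound covers counting error in IFNT3 and not the spread between animals. By edgeR's test ULBP27 stood at 7.38 ± 1.42. SH3D19 stood at 0.72 ± 0.16 (179 ± 36.4 against 109 ± 5.25 CPM) and the adhesion protein FLRT3 at 2.03 ± 0.46. The receptors and enzymes of luteolysis were not called either: ESR1 -0.13 ± 0.40, PGR -0.17 ± 0.21, PTGS2 0.25 ± 0.65, PTGES 0.78 ± 0.70, IFNAR1 0.20 ± 0.21 and IFNAR2 0.09 ± 0.38. SERPINA14 differed by 1.37 ± 1.54 and LGALS3BP by -0.33 ± 0.28. The groups did not overlap in 436 genes, 2.77% of those tested, where chance gives 2.86%. Length of infusion and day of the cycle changed together here, since no vehicle group was biopsied on day 20. The authors' deposited table lists 32 genes at q under 0.05, 15 higher and 17 lower, of which 1 (LRRN4) has reads in a single library.

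**Figure D3:**
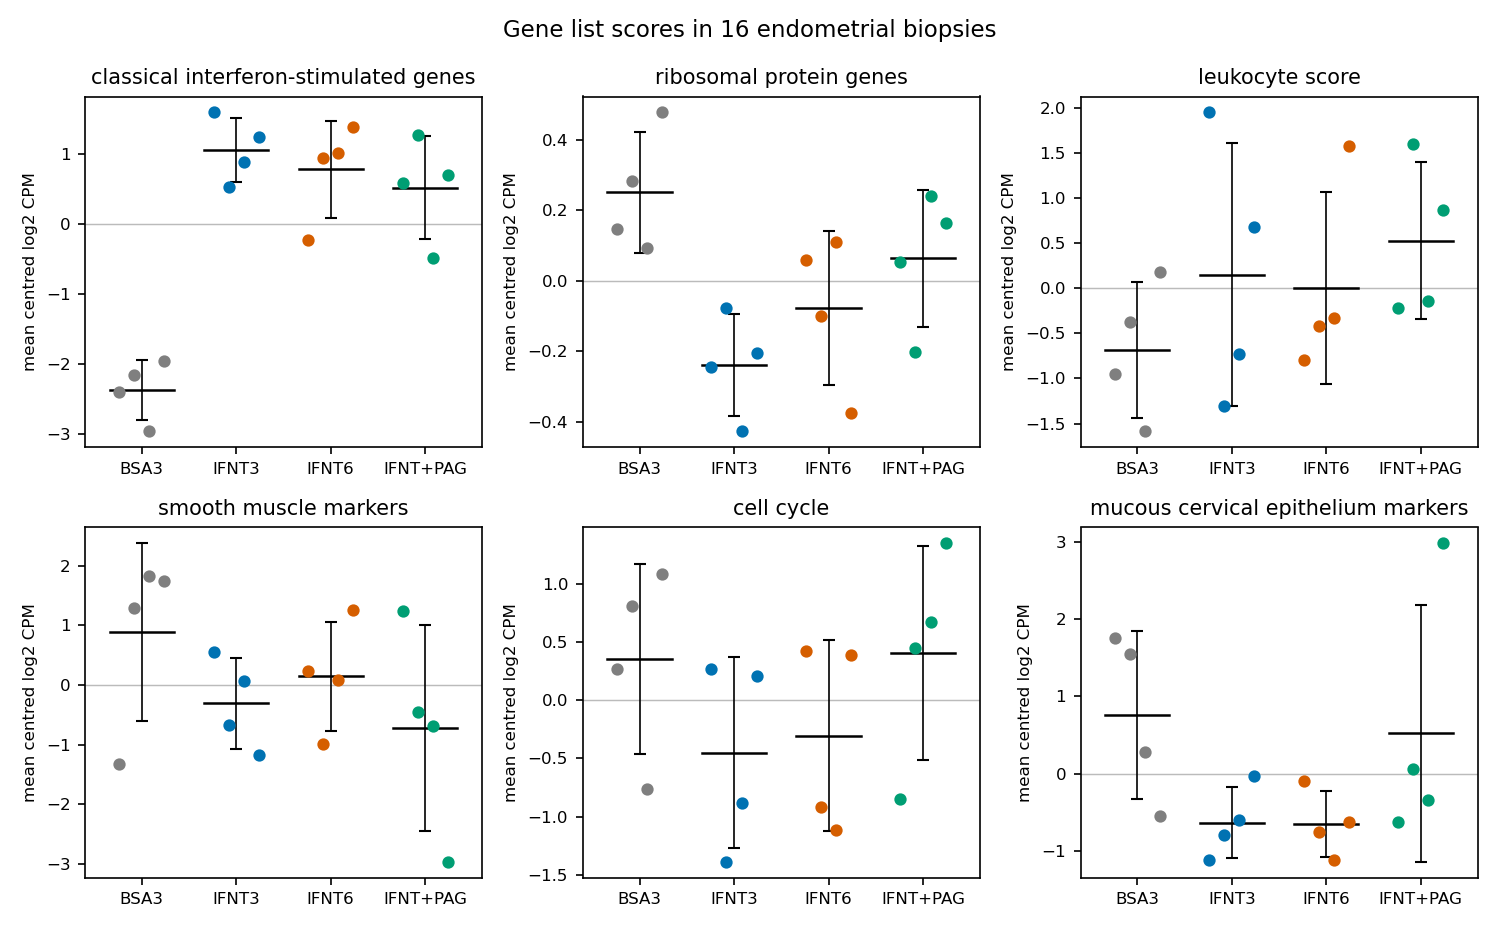
Scores of 6 gene groups in the 4 groups of heifers, as the mean centred log2 CPM of the group's genes, with 1 point per library, a line at the mean and bars for the SD (n = 4). The interferon-stimulated gene score averaged -2.37 in BSA3, 1.07 in IFNT3, 0.78 in IFNT6 and 0.52 in IFNT+PAG.

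The comparison of IFNT+PAG with IFNT6 addressed what PAG added to a course of IFNT at 1 cycle day. In single genes little was found: by edgeR's quasi-likelihood test 0 genes passed, with 515 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999, limma-voom called 0, and DESeq2's Wald test called 1, the elastase inhibitor PI3. The interferon response was present in both groups, at somewhat lower means with PAG: MX1 averaged 1853 ± 1095 CPM against 3378 ± 1137 (log2 fold change -0.87 ± 0.40) and RSAD2 900 ± 392 against 1482 ± 718 (-0.72 ± 0.40). ISG15, MX2, OAS1Y, IFI6, CXCL10, STAT1 and IRF9 differed by -0.22 ± 0.50, -0.33 ± 0.55, -0.46 ± 0.36, -0.24 ± 0.33, -0.33 ± 0.75, -0.39 ± 0.36 and -0.44 ± 0.26, each with an adjusted p of 0.999. The 55 classical interferon-stimulated genes had a median of -0.33 (adjusted p = 1.53e-06, and adjusted p = 0.783 with an estimated correlation), with IFI27 at -0.94 ± 0.44. The list lost its call without IFNT6 replicate 4 (adjusted p = 0.0867, median -0.06) or IFNT+PAG replicate 3 (0.658, median -0.05), and its median was -0.55 without IFNT6 replicate 1 and -0.60 without IFNT+PAG replicate 2; 15 of the 35 splits gave a median as far from 0.

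Genes of the cell cycle and markers of neutrophils and of B and plasma cells were higher with PAG as groups. Cell cycle genes had a median log2 fold change of 0.78, with 45 of 48 above 0 (adjusted p = 1.22e-09, and adjusted p = 0.699 with an estimated correlation). The mitotic kinase CDK1 stood at 1.33 ± 0.49 and MCM3 at 0.80 ± 0.37. All 21 neutrophil markers lay above 0, with a median of 1.27 (adjusted p = 1.53e-06, and adjusted p = 0.699 with an estimated correlation), the calgranulin S100A12 at 2.68 ± 1.15 and the chemokine receptor CXCR2 at 3.24 ± 1.48. B and plasma cell markers had a median of 0.48 over 24 genes (adjusted p = 1.57e-05, and adjusted p = 0.699 with an estimated correlation), with PAX5 at 2.82 ± 0.97 and MS4A1 (CD20) at 2.15 ± 0.94. Other leukocyte lists were not called: T and NK cell markers had a median of 0.13 (adjusted p = 0.434), macrophage and dendritic cell markers -0.09, with 16 of 33 above 0 (adjusted p = 0.996), and mast cell and eosinophil markers -0.09 (adjusted p = 0.747). The 7 red blood cell markers all lay above 0, with a median of 1.02, and were not called either (adjusted p = 0.207). Among the 35 splits of the 8 libraries, the real one included, medians as far from 0 were reached in 6 for cell cycle, 8 for neutrophil, 16 for B and plasma cell and 1 for red blood cell markers (highest other 0.85). By edgeR's quasi-likelihood test, DESeq2 and limma-voom 0 members of these 3 lists passed, with 2 cell cycle genes, 3 neutrophil markers and 2 B and plasma cell markers higher at an unadjusted p under 0.05. The 3 lists kept their call with any 1 library left out. That is weak support, since camera at the preset correlation also called 11 to 25 lists in each of the other 34 splits. With fry 0 of the 40 lists were called in this comparison. The size of the difference also moved. Without IFNT+PAG replicate 4 the median was 0.32 for cell cycle and 0.45 for neutrophil markers. The neutrophil median was 2.32 without IFNT6 replicate 4. The median of B and plasma cell markers was 0.15, 0.20, 0.27 and 2.01 without IFNT6 replicates 1 to 4, and 0.19 without IFNT+PAG replicate 2. The leukocyte score was above 0.8 in 2 of the 4 IFNT+PAG libraries and in 1 of the 4 IFNT6 libraries.

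Inflammatory, epithelial and mucous genes were higher with PAG as groups and stromal markers lower, and all 4 calls ended without IFNT+PAG replicate 4. Inflammatory cytokines and acute phase genes had a median of 0.61 over 34 genes (adjusted p = 2.88e-05, and adjusted p = 0.699 with an estimated correlation), with IL1B at 3.46 ± 1.24 and its antagonist IL1RN at 3.64 ± 1.22. All 25 epithelial markers lay above 0, with a median of 0.47 (adjusted p = 5.77e-05, and adjusted p = 0.699 with an estimated correlation), with the epithelial transcription factor EHF at 0.94 ± 0.44 and RAB25 at 0.93 ± 0.52. The 9 markers of mucous cervical epithelium had a median of 2.04 (adjusted p = 5.07e-05, and adjusted p = 0.699 with an estimated correlation), with the gel-forming mucin MUC5AC at 3.76 ± 1.14, higher when adjusted over the list alone, and BPIFB1 at 3.63 ± 1.29. Stromal fibroblast markers had a median of -0.40 (adjusted p = 2.07e-06, and adjusted p = 0.699 with an estimated correlation), with MFAP4 at -0.72 ± 0.47. By edgeR's quasi-likelihood test, DESeq2 and limma-voom 0 members of these 4 lists passed over all genes. At an unadjusted p under 0.05, 4 inflammatory genes and 5 mucous markers were higher. Without IFNT+PAG replicate 4 all 4 lists lost their call (adjusted p = 0.222, 0.837, 0.267 and 0.234, with medians of 0.16, -0.01, 0.32 and -0.13), and the count of called lists went from 15 to 6; it was 23 without IFNT+PAG replicate 2. The epithelial markers also lost their call without IFNT6 replicate 4 (adjusted p = 0.0866). Of the 35 splits 18, 17, 10 and 9 gave medians as far from 0 for the inflammatory, epithelial, mucous and stromal lists. The inflammatory median was 1.73 without IFNT6 replicate 4, 0.94 without IFNT+PAG replicate 1 and 0.99 without IFNT+PAG replicate 3, and the stromal median -0.22 without IFNT6 replicate 1 and -0.74 without IFNT+PAG replicate 3.

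The named genes of smallest p were APOLD1, an immediate early gene of endothelium (17.6 ± 4.36 against 41.6 ± 14.9 CPM, -1.24 ± 0.28), 1 of the genes with the symbol APOL3 (6.60 ± 3.02 against 2.86 ± 0.71 CPM), PI3 (97.3 ± 170 against 2.92 ± 1.95 CPM), the sulphotransferase GAL3ST2 (3.39 ± 0.95) and the scaffold protein CASS4 (38.9 ± 66.2 against 1.57 ± 1.42 CPM). All 5 failed the test with an adjusted p of 0.999. GAL3ST2 stood at 13.4 CPM in IFNT+PAG replicate 4, against 0.799 to 1.1 in the other IFNT+PAG libraries. PTGS2 averaged 509 ± 597 CPM with PAG against 140 ± 68.8 (1.86 ± 0.67, adjusted p = 0.999), and 1402 CPM came from IFNT+PAG replicate 4. The 31 prostaglandin genes had a median of 0.02 and were not called (adjusted p = 0.347). OXTR, ESR1, PGR and PTGES differed by 0.04 ± 0.68, -0.20 ± 0.40, -0.22 ± 0.21 and 0.46 ± 0.69, IFNAR1 and IFNAR2 by 0.14 ± 0.21 and 0.10 ± 0.38, and SERPINA14 and LGALS3BP by -1.59 ± 1.55 and -0.19 ± 0.28. The groups did not overlap in 172 genes, 1.09% of those tested, where chance gives 2.86%. The authors' deposited table lists 4 genes at q under 0.05, all higher. They are LRRN4 and LOC505033, each with reads in a single library, and TRARG1, with 99.2% of its reads in 1 library. The last is MUC5AC (log2 3.77, q = 0.0457), with 66.3% of its reads in 1 library.

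The comparison of IFNT6 with BSA3 addressed how far 6 days of IFNT moved the endometrium from vehicle, with the cycle day differing between the groups. The interferon-stimulated genes again rose together, 49 of 55 higher and 52 when adjusted over the list alone, with a median log2 fold change of 3.30 (adjusted p = 6.55e-179, and adjusted p = 0.0042 with an estimated correlation). OAS2 rose by 6.06 ± 0.53 and RSAD2 by 5.91 ± 0.50 (adjusted p = 7.2e-05 for both), MX2 by 6.11 ± 0.69, ISG15 by 5.81 ± 0.61, MX1 by 4.50 ± 0.45, IFI6 by 4.33 ± 0.38 and OAS1Y by 4.01 ± 0.41. USP18, which removes ISG15 from proteins and curbs the receptor, rose by 4.63 ± 0.52 (adjusted p = 0.000337) and ZBP1, a sensor of Z-form nucleic acids, by 4.66 ± 0.72 (adjusted p = 0.00326). IFIT3 rose by 5.36 ± 0.77, STAT1 by 2.28 ± 0.37, IRF9 by 2.47 ± 0.27 and LGALS3BP by 1.44 ± 0.29 (adjusted p = 0.024). CXCL10 did not pass edgeR's test (3.51 ± 0.83, adjusted p = 0.0607). It was called with DESeq2, limma-voom, 1 surrogate variable, the leukocyte covariate and without IFNT6 replicate 1.

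Of 16 guanylate binding proteins and interferon gamma response genes 5 were higher, 9 when adjusted over the list alone, with a median log2 fold change of 2.02 (adjusted p = 1.59e-17, and adjusted p = 0.309 with an estimated correlation), GBP4 at 3.18 ± 0.39 and GBP2 at 3.84 ± 0.60. The median was 1.15 without IFNT6 replicate 4. Of 25 genes of MHC class I antigen processing 4 were higher, 15 when adjusted over the list alone, with a median of 0.79 (adjusted p = 3.87e-15, and adjusted p = 0.309 with an estimated correlation), TAP1 at 2.17 ± 0.46 and the proteasome activator PSME2 at 1.05 ± 0.21. Ribosomal protein genes had a median of -0.32 (adjusted p = 4.49e-12, and adjusted p = 0.602 with an estimated correlation), and -0.21 without BSA3 replicate 4. By edgeR's quasi-likelihood test 0 of the 76 passed, with 26 lower at an unadjusted p under 0.05, DESeq2 called 9 and limma-voom 18. RPL13 stood at -0.81 ± 0.19 (adjusted p = 0.0577) and was called with DESeq2, limma-voom, upper-quartile factors, 1 surrogate variable and without IFNT6 replicate 1. None of the hormone receptors or prostaglandin enzymes passed: OXTR stood at 0.24 ± 0.68 (adjusted p = 0.91), ESR1 at -0.80 ± 0.40 (adjusted p = 0.441), and PGR at 0.43 ± 0.21 (adjusted p = 0.433). The rest were PTGS2 at 0.22 ± 0.65, PTGES at -0.02 ± 0.69, IFNAR1 at -0.10 ± 0.21 and IFNAR2 at 0.25 ± 0.38. SERPINA14 stood at 1.67 ± 1.56.

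In all, 194 genes were called between IFNT6 and BSA3, 188 higher and 6 lower, of which 167 changed at least 2-fold (163 higher, 4 lower). The largest rise among the named genes was that of CLEC4F (6.48 ± 1.39, adjusted p = 0.0336), and IFIT2 rose by 5.40 ± 1.06 (adjusted p = 0.0205). Without the 5 libraries of highest leukocyte score CLEC4F stood at 5.48 ± 0.83. There it was below OAS2 (5.99 ± 0.52), RSAD2 (5.91 ± 0.54), MX2 (5.78 ± 0.58) and ISG15 (5.58 ± 0.57). The 4 named genes that fell were CCDC188 (45.8 ± 13.4 to 14.4 ± 4.96 CPM, adjusted p = 0.0128), CRTAP, a partner in collagen hydroxylation (-1.56 ± 0.34, adjusted p = 0.0344), SERF2 (-0.69 ± 0.16, adjusted p = 0.049) and the phospholipase PLD2 (-0.64 ± 0.13, adjusted p = 0.0294). CRTAP, SERF2 and PLD2 lost their call without the 5 libraries of highest leukocyte score, where the folds were nearly the same (-1.52 ± 0.41, -0.70 ± 0.19 and -0.61 ± 0.15) with fewer libraries. They also lost it in a fit of the 8 libraries alone, and SERF2 with RLE factors and with no filter. The 4 genes that fell, CLEC4F, IFIT2, LGALS3BP, TAP1 and PSME2 each lost their call in 4 or more of the 8 removals of 1 library, with a highest adjusted p from 0.0640 (CCDC188, without IFNT6 replicate 3) to 0.183 (SERF2, without IFNT6 replicate 2). The groups did not overlap in 1604 genes, 10.19% of those tested, where chance gives 2.86%, and 191 of the called genes were among them. Leaving out any 1 library moved the count over 1.5-fold: 106, 96, 92 and 105 genes without BSA3 replicates 1 to 4, and 409, 109, 92 and 100 without IFNT6 replicates 1 to 4.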

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

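The tests in this part that were chosen only after the result was seen are the leukocyte score as a covariate, the removal of single libraries in the list tests and the test for cervical epithelium. In 387 groups of 4 libraries (CPM of named genes, list scores and totals) a library was marked where its gap to the nearest of the others, over the group's range, passed Dixon's 95% critical value. For genes the gap and range were taken on log2 CPM with a small offset, while the values printed below are CPM. The rule marked 19 values, 4.9%, where chance marks about 1 in 20 groups. IFNT6 replicate 1 held 6 of them, all lower than the other 3 libraries: MX1 1715 CPM (others 3584 to 4162), OAS1Y 762 (1721 to 1825), STAT1 233 (480.4 to 518), ISG15 208 (683 to 869), IFIT3 92.9 (620.5 to 717) and GAL3ST2 0.0894 (0.424 to 0.513). IFNT+PAG replicate 4 held 5. Of these EHF (176 CPM, others 34.9 to 41.5), GAL3ST2 (13.4, others 0.799 to 1.1), the squamous cervicovaginal epithelium score (2.53, others -0.65 to -0.13) and the score of fatty acid and cholesterol metabolism (0.81, others -0.19 to -0.06) were higher. The total count was lower (18.62 M, others 21.59 M to 21.77 M). In BSA3, IRF9 (63.4 CPM, others 93.8 to 101) and the score of MHC class I antigen processing (-1.15, others -0.58 to -0.53) were low in replicate 3. MYH11 (219 CPM, others 1899 to 2619) and USP18 (5.86, others 7.40 to 7.58) were low in BSA3 replicate 1. In IFNT3, DGAT2 was high in replicate 2 (129 CPM, others 13.3 to 18.4) and TNFSF10 low in replicate 3 (123, others 164 to 169.8). The complement score was high in IFNT+PAG replicate 2 (0.88, others -0.03 to 0.05), and the score of macrophage and dendritic cell markers in IFNT6 replicate 4 (1.35, others -0.13 to -0.05).

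The rise of classical interferon-stimulated genes in IFNT3 was weighed against a larger share of leukocytes in the treated biopsies. With the leukocyte score as a covariate the list's median log2 fold change was 3.09, against 3.44 without it, so a trend with leukocytes does not account for most of the rise. Only the real 1 of the 35 splits gave as many as the 572 genes called between IFNT3 and BSA3 (highest other 0). The same held for the 194 between IFNT6 and BSA3 (1 of 35, highest other 0). The splits alone cannot exclude chance, since the real split is 1 of only 35. A mixed split also puts treated libraries into both groups, which widens the spread and makes calls unlikely. A direct response of endometrial cells to IFNT, the treatment that set the groups apart, may explain the rise. Which cells responded stays open, since whole biopsies were sequenced, and the test leaves room for a change inside leukocytes.

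The lower ribosomal protein genes in IFNT3 were weighed against 3 technical explanations. The median, -0.49, was -0.45 with the leukocyte score as a covariate and -0.51 under RLE factors, the nearer to 0 of the 2 other scalings. Genes of the nearest mean CPM outside the list had a median of 0.13 (-0.01 to 0.26, the range of 95% of 10000 draws), and 0 draws were as low as the list, which argues against a loss of abundant transcripts of all kinds. A lower output of ribosomal protein mRNA under IFNT may be a biological explanation. A shift in cell types other than leukocytes was not tested and stays open, as do transcript length and GC content, for which no values were used here.

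The lists that differed between IFNT+PAG and IFNT6 were weighed against 1 library that stands apart, IFNT+PAG replicate 4, without which the number of lists called was 6, against 15 with it. Cervical epithelium, through which the forceps passed, is a candidate source of RNA in that library, where the mucous cervical score was 2.98, against 1.76 in the highest of the other 15 libraries, and the squamous score 2.53 against 0.79. There 7 of 9 mucous and 10 of 15 squamous markers were at their highest, among them BPIFB1 (2471 CPM, highest other 623), PIGR (1857, 420.3), MUC5AC (1015, 195), KRT6A (69.2, 7.06) and KRT5 (62.2, 16.4). Of the 7 that were not, CREB3L1 (168 CPM) was below the median of the other libraries (299) and FCGBP (47.9, median 13.7), KRT13 (22.8, 7.74), TRIM29 (10.1, 6.52), KRT4 (5.35, 0.303), LY6D (0.613, 0.357) and DSG1 (0.613, 0.430) were above it. Each of the 24 markers also had reads in other libraries, a response of that endometrium to PAG or inflammation stays open, and no sorting step is described that would remove cervical cells.

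Chance could not be excluded for the numbers of lists called: 20 between IFNT3 and BSA3 (14 of 35 splits gave as many, highest other 27), 6 between IFNT6 and IFNT3 (35 of 35, highest other 24). The same held for 15 between IFNT+PAG and IFNT6 (28 of 35, highest other 25) and 21 between IFNT6 and BSA3 (13 of 35, highest other 30). In the comparison of IFNT6 with IFNT3 other splits called up to 4 times the real number. The other 34 splits called a median of 17 to 19 of the 40 lists in the 4 comparisons, and each called at least 1. Camera at the preset correlation thus called many lists whatever the grouping. Its adjusted p alone is therefore no evidence of a difference between groups. With an estimated correlation 1, 0, 0 and 1 lists were called in the 4 comparisons, in the order above. In the simulated data, where genes varied independently, camera called 0 of 20 unchanged lists. Both results go with genes of a list moving together more than the preset allows, but that cause was not tested directly. By count, 0 genes were called by edgeR's quasi-likelihood test between IFNT6 and IFNT3 (35 of 35 splits gave as many, highest other 0) and between IFNT+PAG and IFNT6 (35 of 35, highest other 1). Any split gives at least 0, so for these 2 counts the splits say nothing about chance. At an unadjusted p under 0.05 there were 732 and 515 genes, and DESeq2 called 11 and 1 and limma-voom 0 and 0.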

How the results depend on the processing

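The leukocyte score as a covariate, the fit without the 5 libraries of highest leukocyte score and the removal of single libraries in the list tests were chosen only after the result was seen. The 572 genes called between IFNT3 and BSA3 became 1034 with 1 surrogate variable, 1596 with DESeq2, 1228 with limma-voom and 203 without the 5 libraries of highest leukocyte score (153 shared with the 572). It was 231 to 917 with 1 library left out (245, 256 and 231 without BSA3 replicates 2, 3 and 4, and 272, 917, 368 and 276 without IFNT3 replicates 1 to 4). RLE and upper-quartile factors, no filter, the stricter filter, the covariate, the 8 libraries alone and the 2-fold minimum gave 383 to 741. The 194 genes between IFNT6 and BSA3 became 297 with a surrogate variable, 591 with DESeq2 and 1547 with limma-voom. It was 92 to 409 with 1 library left out (106, 96, 92 and 105 without BSA3 replicates 1 to 4, and 409, 109, 92 and 100 without IFNT6 replicates 1 to 4). The other alternatives gave 156 to 263. The 0 genes between IFNT6 and IFNT3 became 11 with DESeq2, and the 0 between IFNT+PAG and IFNT6 became 1 (PI3) with DESeq2. Every other alternative run, limma-voom and each removal of 1 library included, gave 0. Of the lists called, 20 between IFNT3 and BSA3 became 1 with an estimated correlation and 6 with fry (15 to 24 with 1 library left out). For IFNT6 and IFNT3, 6 lists became 0 with an estimated correlation, 0 with fry, 13 without the 5 libraries and 4 to 20 with 1 library left out (12, 15 and 14 without IFNT3 replicates 1, 2 and 3, and 20 without IFNT6 replicate 4). For IFNT+PAG and IFNT6, 15 became 0 and 0 by those 2 tests, 30 with the leukocyte covariate and 6 to 23 with 1 library left out (23 and 6 without IFNT+PAG replicates 2 and 4). For IFNT6 and BSA3, 21 became 1 and 1 (19 to 26 with 1 library left out). A fit with fewer libraries has less power; for the other changes the cause was not tested. Among 103 genes named for IFNT3 and BSA3, of which 54 were called, 21 stayed called under every alternative and 33 lost their call in at least 1. Of 1852 values 171 were weaker, 78 stronger and 0 reversed. For IFNT6 and BSA3, 15 of 27 called genes stayed called throughout (93 of 720 values weaker, 18 stronger, 0 reversed), and for the 2 other comparisons 5 and 1 values became called, each with DESeq2. The alternatives set down for FPKM or TPM (pseudocount and filter) were not run, since counts were used. Depth limits rare transcripts, for which 3 counts over a group was the floor, and the spread between animals limited the other genes more.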

Other observations

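The tests in this part, all on relations and genes picked from these libraries, were chosen only after the result was seen. Transcripts of 3 members of the ULBP family, ligands that stressed or infected cells show to the NK cell receptor NKG2D, were nearly absent from IFNT3. ULBP3 averaged 4.80 ± 3.06 CPM in BSA3, 0.445 ± 0.264 in IFNT3, 11.9 ± 8.14 in IFNT6 and 5.15 ± 6.69 in IFNT+PAG. ULBP11 averaged 1.14 ± 0.763, 0.0218 ± 0.0437, 2.87 ± 2.05 and 0.895 ± 0.904 CPM in the same order, and ULBP27, with 0 reads in IFNT3, 0.26 ± 0.119 in BSA3, 0.936 ± 0.475 in IFNT6 and 0.519 ± 0.741 in IFNT+PAG. None of the 3 passed edgeR's quasi-likelihood test. ULBP3 and ULBP11 stood at -3.42 ± 1.32 and -5.34 ± 1.73 in IFNT3 against BSA3 (adjusted p = 0.164 and 0.103; ULBP27 0.0632) and at 4.72 ± 1.39 and 6.67 ± 1.76 in IFNT6 against IFNT3 (adjusted p = 0.981 for both). The authors' deposited table of IFNT6 against IFNT3 lists all 3 as higher (q = 0.000964 for ULBP3, 0.00651 for ULBP11 and 0.000896 for ULBP27). Reads can be shared between these paralogs, so the 3 genes are not independent observations.

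OXTR differed more between day-20 libraries than between their groups, and a weaker interferon response in the same biopsy is a candidate explanation, since IFNT is known to hold the receptor down. The 2 libraries of highest OXTR, IFNT+PAG replicate 3 (71.3 CPM) and IFNT6 replicate 1 (70.7, others 9.19 to 30.8), had MX1 at 797 and 1715 CPM. BSA3, biopsied on day 17, had the lowest mean interferon-stimulated score (-2.37) but a lower mean OXTR than either of these 2 libraries. No vehicle group shows the level of OXTR without IFNT on day 20. Over the 8 day-20 libraries OXTR fell with the score of classical interferon-stimulated genes, with a Pearson r of -0.839 (exact permutation p = 0.0117, adjusted over 5 relations p = 0.0587) and a Spearman rho of -0.714 (p = 0.0576, adjusted p = 0.24). Without those 2 libraries r was -0.275. Over the 12 treated libraries, centred in each group, it was -0.452 (p = 0.187 over pairings within groups, adjusted p = 0.312; rho -0.308, p = 0.376), and 0.182, with the sign turned, without the same 2. At a rho of -0.714 on 8 libraries, 2 animals that differ for another reason cannot be told apart from the proposed link. The score of leukocytes (r = -0.345, p = 0.395; rho -0.190, p = 0.665) and that of epithelial markers (r = 0.186, p = 0.685; rho 0.452, p = 0.267) were not clearly related to OXTR. ESR1, over the 8 libraries, had an r of -0.744 (p = 0.0383, adjusted p = 0.0959; rho -0.643, p = 0.0962) and -0.127 without the same 2. Over the 12 treated libraries centred in each group its r was -0.808 (p = 0.00622, adjusted p = 0.0311; rho -0.769, p = 0.0124, adjusted p = 0.0622), and -0.644 without the 2 farthest. PGR had an r of 0.586 over the 8 libraries (p = 0.143, rho 0.476, p = 0.243) and 0.470 over the 12 (p = 0.151). Without the same 2 libraries these were -0.151 and 0.0812. Its direction over the 8 libraries rests on them, as does most of its size over the 12.

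Lists called by camera at a preset correlation, but not with an estimated one, and not described above were mostly small in effect. Between IFNT3 and BSA3 they were endothelial markers (median log2 fold change -0.39, adjusted p = 0.0217), mucous cervical epithelium markers (-1.12, adjusted p = 0.0155) and the unfolded protein response (0.27, adjusted p = 0.0487). All 3 lost their call without BSA3 replicate 1 (adjusted p = 0.117, 0.0740 and 0.117) or IFNT3 replicate 1 (0.0751, 0.0533 and 0.229). Endothelial markers also lost it without IFNT3 replicates 2 or 3 (0.0553 and 0.0849), and the unfolded protein response without BSA3 replicate 3 or IFNT3 replicate 4 (0.206 and 0.157). Between IFNT+PAG and IFNT6, smooth muscle markers (-0.35), endothelial markers (-0.22), extracellular matrix remodelling (-0.22), WNT signalling (-0.16), immediate early genes (0.27) and fatty acid and cholesterol metabolism (0.32) all lost their call without IFNT+PAG replicate 4 (adjusted p = 0.364, 0.364, 0.600, 0.364, 0.863 and 0.809). Ribosomal protein genes (0.13) lost it without IFNT6 replicate 4 or IFNT+PAG replicate 3 (0.556 and 0.0806). Smooth muscle markers and matrix genes also lost it without IFNT6 replicate 4 (0.143 and 0.892). The same held for WNT signalling, immediate early genes and matrix genes without IFNT6 replicate 1 (0.294, 0.309 and 0.196), and matrix genes without IFNT+PAG replicate 1 (0.225).

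Between IFNT6 and BSA3, 17 further lists were called at a preset correlation, and all 17 lost their call with an estimated one (adjusted p from 0.338 to 0.726). Higher medians, with the adjusted p at the preset correlation, were those of the interferon receptor and JAK-STAT genes (0.55, 1.34e-11), MHC class II (0.95, 3e-05), complement (0.80, 0.000316), immune checkpoint and tolerance (0.53, 0.0157) and pattern recognition and inflammasome (0.77, 2.03e-07). So were those of apoptosis (0.54, 7.75e-07), the unfolded protein response (0.20, 0.0149), immediate early genes (0.28, 0.00393), T and NK cell markers (1.32, 2.21e-06) and macrophage and dendritic cell markers (1.13, 4.98e-06). Lower medians were those of extracellular matrix remodelling (-0.44, 6.52e-05), cell cycle (-0.62, 6.52e-05), ciliated cell markers (-0.51, 0.00378) and stromal fibroblast markers (-0.27, 0.0344). Endothelial markers (-0.25, 0.00231), smooth muscle markers (-0.92, 0.00118) and mucous cervical epithelium markers (-1.83, 0.00123) were also lower. Medians as far from 0 also came up among the 35 splits of the 8 libraries, the real split included. In the order listed, the numbers of splits were 2, 4, 3, 7, 3, 1, 17, 11, 2 and 7 for the higher lists. For the lower lists they were 11, 12, 6, 12, 9, 8 and 2. The checkpoint list lost its call without BSA3 replicate 3 or IFNT6 replicate 4 (adjusted p = 0.0751 and 0.256), the unfolded protein response without the same 2 (0.104 and 0.425). Ciliated markers lost it without BSA3 replicate 1 or IFNT6 replicate 3 (0.0785 and 0.184), and stromal markers without BSA3 replicates 2 or 4 or IFNT6 replicates 2 or 4 (0.106, 0.283, 0.118 and 0.0996).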
